A study of Mus musculus with 4 samples.

How the data were processed

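Total RNA from 4 mouse cell samples was measured on 1-colour Affymetrix arrays, 1 array per sample. The samples were mouse embryonic fibroblasts (MEF), the induced pluripotent stem (iPS) cell lines 178B5 and 492B4, and the embryonic stem (ES) cell line v6.5. Per the labels' protocols, the fibroblasts were grown in medium with serum, and the 3 pluripotent lines were grown on a layer of mitotically inactivated SNL fibroblasts. The MEF and both iPS lines carried a mixed DBA/2, C57BL/6 and 129S4 background, and the ES line was an F1 of 129 and C57BL/6, so strain differed between ES and the other samples.

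The authors deposited 1 table of values on a log scale for 28853 probe sets and 4 arrays. Per the submitters' processing notes these values came from GCRMA, which corrects background, normalizes between arrays and summarises the probes of a probe set; its version is not given in the sources used here. The log base was not stated and was taken as log2 for the deposited values, so every log2 difference and every fold rests on that reading. In the deposited table the median of each probe set over the 4 arrays was 0 within 1e-06 for all 28853 probe sets. The table therefore held differences between arrays and no expression levels, and a value could not be set against background. Higher values were taken as brighter signal. The column medians were 0.0419 for MEF, -0.0145 for iPS 178B5, -0.0250 for iPS 492B4 and 0.0158 for ES, with standard deviations of 0.887, 0.195, 0.282 and 0.267. No scan date, slide or batch was given, and no column lay outside the 4 samples.

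Probe sets were named through the platform annotation. Of them, 21789 had 1 gene symbol, 1621 had several and 5443 had none; only those with 1 symbol were used. The gene identifiers of 21698 probe sets matched the gene table of assembly GRCm38.p6, and 0 symbols changed. Coordinates were not used. The values of a gene's probe sets were averaged, which gave 19938 genes, 18939 of them with 1 probe set and 999 with several.

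The main comparison set the 3 pluripotent lines against MEF. Linear models were fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and Benjamini-Hochberg adjustment over all 19938 genes. A gene was called at an adjusted p under 0.05 and a difference of at least 1 log2. This fit had 2 residual degrees of freedom, and its spread came from the 3 lines. The lone MEF array was assumed to vary like them. A fit with 3 groups (MEF, iPS, ES), with 1 residual degree of freedom from the 2 iPS lines, served iPS against ES, iPS against MEF and ES against MEF. Here the lone ES and MEF arrays were assumed to vary like the iPS lines. The 2 iPS lines were compared with each other by value, without a test. Separate cell lines stood as replicates, and nothing in the labels describes repeat cultures, so p-values measure the spread between these samples only. The number of arrays limits the precision of every value.

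The plan made before the data were examined differed from this in 3 settings, because it assumed levels rather than centred differences. It had a variance trend over mean level, the probe set with the highest mean for each gene, and a filter at the table's median. The trend had no level to follow, the highest mean favoured probe sets bright on MEF, and the filter removed 0 probe sets. The planned trend and the planned probe set rule were run as alternatives. Pearson correlations between arrays, also planned, were replaced by root mean square differences, since the centring fixes the correlations in part.

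The comparisons covered 30 gene lists with 823 entries, 745 of them measured, all fixed before the data were examined. They held core pluripotency, naive state, reprogramming factor, primed and early lineage, epithelial, fibroblast matrix, mesenchymal identity, Hox cluster, DNA methylation, Polycomb, germline, 2-cell-like, imprinted, sex-linked, cell cycle, p53 and cell cycle inhibitor, glycolysis, oxidative phosphorylation, interferon, signalling target (Wnt, TGF-beta and BMP) and reference genes. Marker lists for macrophages, endothelial, erythroid, keratinocyte, neural, skeletal muscle, skeletal and fat, trophoblast and primitive endoderm cells completed the set. Lists share some members. Each was tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the 30 lists. Members called were counted over all genes and adjusted over the list alone. Between the iPS lines, a list's median was placed among 10000 random lists, as a description of these arrays. The random lists were matched, in 20 bins, on the size of the difference between MEF and the mean of the lines. The direction of that difference was not matched, and genes were drawn singly.

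Genes were named by a rule fixed beforehand. For the main comparison it took the 10 largest called rises and falls in which every line differed from MEF by at least 1 log2. It added up to 4 called members per list and members called against a list's majority. For iPS against ES it took the 8 largest differences each way among genes with both lines at least 1 log2 from ES. For the iPS lines it took the 6 largest each way and list members at least 1 log2 apart. Predicted loci were left out, and 20 genes were always to be named. Of these, Ddx3y, Mirg and H19 had no probe set of their own and were not analysed here. Genes named outside the rule are marked as chosen after their values were seen.

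The scripts were tested on simulated data with 200 changed genes among 19938. For pluripotent against MEF, 6% of changes of 1 log2 and 100% of changes of 3 log2 were recovered, with 4 false calls. For iPS against ES the simulation was run with both available spreads. With the spread of the 3 lines, 4% and 100% were recovered, with 18 false calls. With the spread of the 2 iPS lines, 51% and 100% were recovered, with 14 false calls. Noise was drawn from the moderated spreads, which range less widely than the genes' own, so these shares need not hold on the real arrays. There Lama1 differed by 4.50 log2 between the lines and MEF, and Mmp3 by -4.54 log2 between iPS and ES. Neither was called, so the absence of a call does not mean the absence of a large difference. Among 100 simulated lists of 30 genes, camera found the list that had been shifted by 1 log2. Of the unshifted lists 2 had an unadjusted p under 0.05. Lists whose genes vary together were not simulated, so this result does not bear on such lists. Against MEF the estimated correlations of the real lists ran from -0.117 (erythroid markers) to 0.660 (Hox cluster). With the estimated correlations 0 real lists passed against MEF. In that setting camera's test rests on the residual degrees of freedom, 2 here and 1 for iPS against ES. So few leave it little power at any correlation. The cell cycle list did not pass either, though its estimated correlation, 0.006, lay below the preset 0.01. A list that fails there is therefore not shown to owe its result to genes that vary together.

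Alternatives covered array centring, probe set choice, variance model, fold minimum, left-out lines and the untested counts. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.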

Results

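Gene expression was compared between mouse embryonic fibroblasts and 3 pluripotent stem cell lines, with 1 array each. The lines were iPS 178B5 and iPS 492B4, obtained by reprogramming somatic cells, and ES v6.5, derived from an embryo. All values are log2 differences between arrays, with the log base taken as 2. The root mean square difference over 19938 genes was 1.05 between MEF and iPS 178B5, 1.12 between MEF and iPS 492B4, and 0.980 between MEF and ES. It was 0.276 between the 2 iPS lines, 0.404 between iPS 178B5 and ES, and 0.486 between iPS 492B4 and ES.

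The main comparison asked which genes separate pluripotent cells from fibroblasts. Of the 10 largest rises 7 are members of the core pluripotency list. Dppa5a, an RNA-binding protein of pluripotent cells, rose by 8.06 ± 0.21 log2 (SD, n = 3 lines). Tdgf1, a co-receptor for Nodal, rose by 7.22 ± 0.06 log2, and Pou5f1, a central transcription factor of pluripotency, rose by 6.30 ± 0.12 log2. Of the 10 largest falls 4 (Lox, Ogn, Col12a1 and Fbln5) are members of the fibroblast matrix list. Aspn, a small proteoglycan, fell by 6.24 log2 (SD 0.69, n = 3), and Lox, which crosslinks collagen and elastin, fell by 6.17 log2 (SD 1.85, adjusted p = 0.0462).

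In limma's test 3512 of 19938 genes (17.6%) were called, 1576 higher and 1936 lower in the pluripotent lines. With the arrays centred on the reference genes instead, a choice made after seeing the data, the split was 1332 higher and 2510 lower, and with each array's median set equal it was 1700 and 1730. The median difference from MEF over all genes was -0.108 for iPS 178B5, -0.131 for iPS 492B4 and -0.065 for ES as deposited, and the reference genes' median was -0.141 on the MEF array against 0.020, 0.064 and -0.019 on the lines. Without iPS 178B5 the number called was 1357. In the 3-group fit 4216 genes were called for iPS against MEF, 1981 higher and 2235 lower (1586 and 2812 with reference centring, 2265 and 2022 with equal array medians, which turned the balance). For ES against MEF 3990 were called, 1823 higher and 2167 lower (1629 and 2618, and 1959 and 2097, under the same settings).

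**Figure D1:**
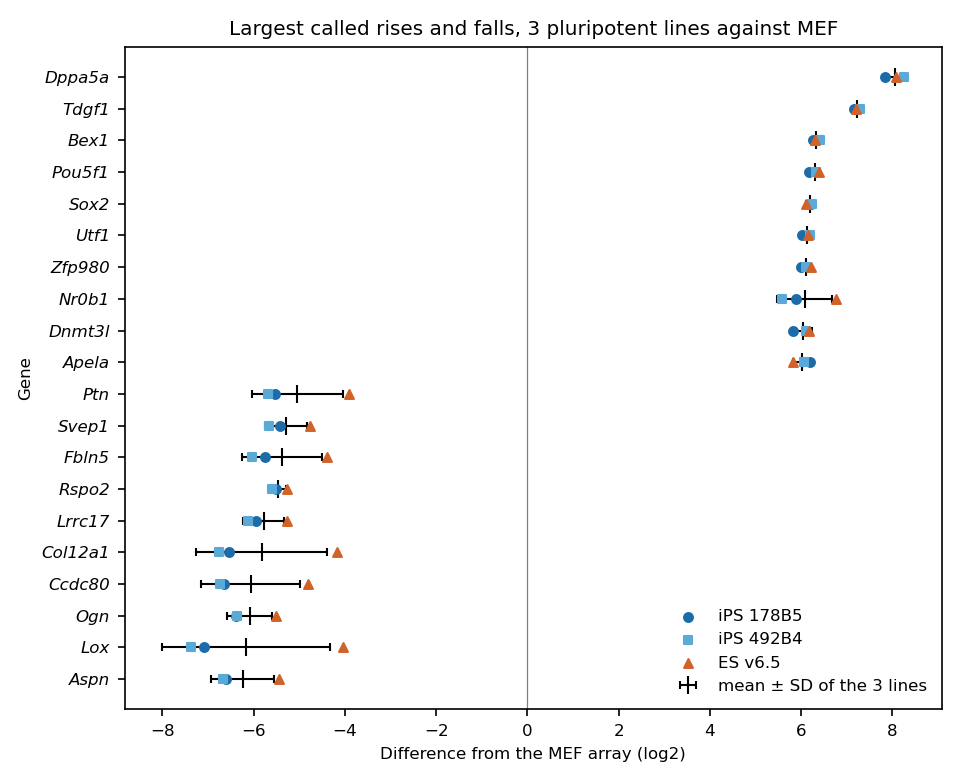
Difference from the MEF array (log2, horizontal axis) for the 10 largest called rises and the 10 largest called falls (vertical axis), with 1 symbol per line and the mean ± SD of the 3 lines in black. Among the rises the SD runs from 0.06 for Tdgf1 to 0.61 for Nr0b1, and among the falls, in which the ES line lies nearest to MEF, from 0.16 for Rspo2 to 1.85 for Lox.

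The remaining large rises were Bex1 (6.33 log2), Sox2 (6.18 log2), Utf1 (6.13 log2), Zfp980 (6.10 log2), Nr0b1 (6.08 log2), Dnmt3l (6.04 log2) and Apela (6.02 log2), the last a ligand of the apelin receptor. The remaining large falls were Ogn (-6.08 log2), Ccdc80 (-6.07 log2), Col12a1 (-5.82 log2), Lrrc17 (-5.78 log2), Rspo2 (-5.46 log2), Fbln5 (-5.38 log2), Svep1 (-5.29 log2) and Ptn (-5.04 log2). Without iPS 178B5, 4 of these falls were not called: Lox (adjusted p = 0.109), Col12a1 (0.0782), Ptn (0.0582) and Ccdc80 (0.0504). Without iPS 492B4, Lox (0.0824) and Col12a1 (0.0548) were not called, nor was Lox with each array's median set equal (0.0525).

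The core pluripotency list, which holds factors and markers of the pluripotent state, rose, with 40 of 46 measured members higher and 1 lower (42 and 1 adjusted over the list alone). Its median was 3.63 log2 (camera adjusted p = 1.68e-27; adjusted p = 0.33 with an estimated correlation). Il6st, the shared receptor subunit for LIF and interleukin-6, fell by 1.83 log2. In the naive state list, named for the ground state of ES cells, 12 of 15 members rose (13 adjusted over the list alone), among them Nanog at 6.00 log2, Esrrb at 5.10 log2 and Tfcp2l1 at 4.77 log2. Its median was 4.10 log2 (adjusted p = 4.59e-12; adjusted p = 0.37 with an estimated correlation). Of the 8 reprogramming factors 4 rose and 1 fell, with the same counts adjusted over the list alone and a median of 2.26 log2 (adjusted p = 0.00145; adjusted p = 0.385 with an estimated correlation). Lin28a rose by 4.08 log2 and Glis1 fell by 1.39 log2, the latter not called without iPS 178B5 (adjusted p = 0.0521). Klf4 at 0.18 log2 (adjusted p = 0.652) and Myc at -0.65 log2 (adjusted p = 0.545) were not called.

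Epithelial genes rose, with 22 of 31 higher (24 adjusted over the list alone) and a median of 2.43 log2 (adjusted p = 2.13e-15; adjusted p = 0.33 with an estimated correlation). Cdh1, the adhesion molecule E-cadherin, rose by 5.87 ± 0.11 log2, and the tight junction genes Cldn6 and Cldn4 rose by 5.62 and 4.54 log2. Epcam rose by 4.15 log2. The cell cycle list rose, with 28 of 39 higher (29 adjusted over the list alone), including Bub1, Mybl2 at 4.17 log2, Mcm10 at 2.87 log2 and Cdt1 at 2.86 log2. Its median was 1.71 log2 (adjusted p = 3.75e-19; adjusted p = 0.305 with an estimated correlation).

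Fibroblast matrix genes fell, with 24 of 43 lower (37 adjusted over the list alone) and a median of -3.22 log2 (adjusted p = 2.53e-10; adjusted p = 0.572 with an estimated correlation). The collagen genes Col1a1 (-4.61 log2) and Col1a2 (-4.76 log2) were called with adjusted p of 0.0326 and 0.0337. Neither was called without iPS 178B5 (0.0923 and 0.0927), and Col1a2 was not called without iPS 492B4 (0.0547). The number of members that fell was 41 without ES, 9 without iPS 178B5 and 13 without iPS 492B4. Leaving out a line was planned, while the count per list in those fits was added after seeing the data. Mesenchymal identity genes fell, with 33 of 44 lower (39 adjusted over the list alone) and a median of -3.16 log2 (adjusted p = 5.62e-13; adjusted p = 0.552 with an estimated correlation). Tgfb3 fell by 5.03 log2, Tbx15 by 4.38 log2, Osr1 by 4.34 log2 and the smooth muscle gene Cnn1 by 4.13 log2. Without iPS 178B5 the count was 21 and Tgfb3 was not called (adjusted p = 0.0772). Thy1, a surface marker of fibroblasts, stood at -3.07 log2 and was not called (adjusted p = 0.0717), and was called without ES (-3.70 log2, adjusted p = 0.00187) or with reference centring (-3.23 log2, adjusted p = 0.0419).

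Hox cluster genes, which set position along the body axis, fell, with 24 of 37 lower (24 adjusted over the list alone) and a median of -1.55 log2 (adjusted p = 1.06e-09; adjusted p = 0.572 with an estimated correlation). Hoxc8 fell by 3.68 log2, Hoxd13 by 3.68 log2, Hoxd10 by 3.58 log2 and Hoxa11 by 3.05 log2. Without iPS 178B5 the count was 9 and Hoxc8 was not called (adjusted p = 0.067).

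Among chromatin regulators, 9 of 13 genes of the DNA methylation list rose (10, and 1 lower, adjusted over the list alone), with a median of 1.61 log2 (adjusted p = 9.71e-07; adjusted p = 0.385 with an estimated correlation). The methyltransferase gene Dnmt3b rose by 3.52 log2, Tet1, which oxidises methylcytosine, by 4.48 log2 and Uhrf1 by 2.22 log2. In the Polycomb list 9 of 20 rose and 2 fell, with the same counts adjusted over the list alone and a median of 1.07 log2 (adjusted p = 0.000132; adjusted p = 0.355 with an estimated correlation). Cbx7 rose by 3.89 log2, Phc1 by 3.33 log2, Jarid2 by 3.04 log2 and Mtf2 by 2.68 log2, while Bmi1 fell by 1.88 log2 and Phc3 by 1.51 log2. Without iPS 178B5 neither of these falls was called (adjusted p = 0.0622 and 0.0899). Germline genes rose, with 16 of 34 higher (17 adjusted over the list alone) and a median of 1.55 log2 (adjusted p = 7.6e-10; adjusted p = 0.385 with an estimated correlation). Among them Tdrd12 and Mael act in the piRNA pathway. Mael rose by 5.21 log2, Kit by 3.50 log2 and Rnf17 by 3.31 log2. Without iPS 178B5 the germline count was 5 and Mael was not called (adjusted p = 0.0501), and without iPS 492B4 Kit was not called (adjusted p = 0.0512). The 2-cell-like list had a median of 0.49 log2 (camera adjusted p = 0.000901, and 0.552 with an estimated correlation). Of 17 measured members 2 were called higher (1 adjusted over the list alone), beside 1576 of all 19938 genes called higher. The list holds 32 genes, and those without a probe set of their own include Zscan4c and Dux, so it covers the 2-cell-like state only in part. With either iPS line left out the count was 1, as Tdpoz3 (1.08 log2) was not called without iPS 178B5 (1.01 log2) or without iPS 492B4 (1.00 log2). With reference centring and all lines kept, Tdpoz3 stood at 0.92 log2, under the fold minimum.

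Glycolysis genes rose, with 8 of 22 higher (9 adjusted over the list alone) and a median of 0.51 log2 (adjusted p = 7.88e-05; adjusted p = 0.572 with an estimated correlation). The glucose transporter gene Slc2a3 rose by 4.43 log2, Aldoc by 4.42 log2, Pdk1 by 2.23 log2 and the lactate exporter gene Slc16a3 by 2.16 log2. Without iPS 178B5 the count was 5 and Aldoc was not called (adjusted p = 0.0667), without iPS 492B4 1 gene was lower, and over genes with 1 probe set only, a choice made after seeing the data, the median was 1.24 log2. None of 38 oxidative phosphorylation genes was called by limma (0 adjusted over the list alone), with a median of 0.09 log2 (adjusted p = 0.143) that was -0.08 log2 with reference centring, 0.16 log2 with equal array medians and 0.05 log2 without iPS 178B5. Interferon genes fell, with 11 of 42 lower and 1 higher (14 and 1 adjusted over the list alone) and a median of -0.53 log2 (adjusted p = 0.0283; adjusted p = 0.572 with an estimated correlation). Tlr4 fell by 3.08 log2, Sting1 by 3.09 log2 and Ifit3 by 2.57 log2, while Ifitm1 rose by 3.70 log2. The list did not pass with reference centring (adjusted p = 0.0551), and without iPS 178B5 the number lower was 3 and Sting1 was not called (adjusted p = 0.0611). Without ES 2 were higher. The trophoblast list rose, with 3 of 12 higher and 1 lower (4 and 1 adjusted over the list alone) and a median of 0.78 log2 (adjusted p = 0.00779; adjusted p = 0.572 with an estimated correlation). Tfap2c rose by 3.33 log2, Ascl2 by 2.34 log2 and Hand1 by 1.34 log2, and Gata3 fell by 1.76 log2. Without iPS 178B5 Hand1 and Gata3 were not called (adjusted p = 0.0532 and 0.105).

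The other lists did not pass camera's test against MEF. Of 39 imprinted genes 4 were higher and 9 lower (4 and 9 adjusted over the list alone; adjusted p = 0.692), and without iPS 178B5 3 higher and 3 lower. Phlda2 rose by 5.44 log2, Zdbf2 by 2.87 log2 and Peg10 by 1.81 log2, and Osbpl5 fell by 2.86 log2. Zdbf2 was not called without iPS 178B5 (adjusted p = 0.0823). Dlk1 fell by 2.31 log2 (adjusted p = 0.0216), and was not called without iPS 178B5 (0.0696). Igf2 (-3.21 log2, adjusted p = 0.121), Meg3 (-0.82 log2, 0.182) and Rian (0.45 log2, 0.0859) were not called, and Igf2 was called without ES (-4.06 log2, adjusted p = 0.00187). Signalling targets had 5 of 27 higher and 4 lower (6 and 6 adjusted over the list alone; adjusted p = 0.547), with Lefty2 at 3.41 log2, Lefty1 at 3.31 log2, Nodal at 3.19 log2 and Id3 at -3.07 log2. Of the 4 that were lower (Id3, Pmepa1 at -2.35 log2, Msx1 at -1.47 log2 and Msx2 at -1.20 log2), 0 were called without iPS 178B5, with adjusted p of 0.0741, 0.0634, 0.0792 and 0.0609. Without ES the balance turned, to 6 higher and 9 lower, and without iPS 492B4 it was 6 and 5. In the p53 and cell cycle inhibitor list 5 of 25 were lower (5 adjusted over the list alone; adjusted p = 0.397), including Cdkn2b at -2.74 log2, Ccnd2 at -2.51 log2, Fas at -2.34 log2 and Cdkn2c at -2.10 log2. Without iPS 178B5 3 were lower and Ccnd2 was not called (0.0926), and without ES 1 was higher. The primed and early lineage list had 3 of 31 higher and 3 lower (3 and 3 adjusted over the list alone; adjusted p = 0.262), with Otx2 at 4.88 log2, Dnmt3a at 1.61 log2, Pdgfra at -2.05 log2 and Fgf5 at -1.35 log2. Without iPS 178B5 Dnmt3a (0.0604) and Fgf5 (0.131) were not called, and without iPS 492B4 Fgf5 (0.0507) and Pdgfra (0.0725) were not. Fgf5 was also not called with equal array medians (0.0525). The counts were 1 higher and 1 lower without iPS 178B5, 4 and 1 without iPS 492B4, and 8 and 4 without ES.

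Markers of other cell types were counted in the same way. Adjusted p values were 0.0954 for macrophage markers (median -0.37 log2, 17 of 19 below 0 and 1 called, Laptm5 at 3.11 log2), 0.17 for endothelial markers (2 of 16 higher, 2 lower, among them Erg at -1.93 log2) and 0.967 for erythroid markers (0 of 9 called). They were 0.449 for keratinocyte markers (2 of 14 higher, Sfn at 3.46 log2 and Krt17 at 2.79 log2) and 0.924 for neural markers (3 of 17 lower, among them Map2 at -2.41 log2). For skeletal muscle markers the value was 0.397 (1 of 19 lower, Acta1 at -2.64 log2) and for skeletal and fat markers 0.0954 (1 of 18 higher, 6 lower). In that list Alpl, also a marker of pluripotent cells, rose, and Pparg fell by 2.42 log2. Of 20 primitive endoderm markers 1 was lower, Pdgfra (0 adjusted over the list alone; adjusted p = 0.597), and without ES 6 were higher. Adjusted over the list alone, the counts of the other marker lists in this group were the same. Without iPS 178B5, 1 skeletal and fat marker was higher and 1 lower, 0 endothelial markers were higher and 1 lower, 1 neural marker was lower, and Acta1 was not called (adjusted p = 0.0519). Without ES, 2 macrophage and 2 skeletal muscle markers were higher and 2 of each lower. Without iPS 492B4, and without ES, 1 neural marker was higher. The reference genes had 2 of 16 higher and 2 lower (2 and 2 adjusted over the list alone; adjusted p = 0.0682), with 1 and 1 without iPS 178B5 and 1 and 2 without iPS 492B4. Tfrc rose by 2.77 log2 and Gusb fell by 1.53 log2; B2m (-1.43 log2) was not called without iPS 178B5 (adjusted p = 0.0954), and Tbp (1.02 log2) stood at 0.86 log2 with reference centring and was not called. None of 7 sex-linked genes was called by limma (0 adjusted over the list alone; adjusted p = 0.967), and without ES 1 was higher and 1 lower. The sex-linked, neural and keratinocyte lists had medians of -0.07, -0.10 and -0.02 log2 while camera's direction was up, and with equal array medians they were 0.01, -0.02 and 0.05 log2 and with reference centring -0.23, -0.26 and -0.18 log2; the keratinocyte median was 0.01 log2 without iPS 178B5 and without ES and -0.04 log2 without iPS 492B4, and the sex-linked one -0.13 log2 without iPS 492B4 and -0.04 log2 without ES. Xist was 1.42 log2 above MEF on the ES array, -0.10 log2 on iPS 178B5 and 0.01 log2 on iPS 492B4. The Y-linked genes Kdm5d (-1.39 log2, adjusted p = 0.0549), Eif2s3y (0.24 log2, 0.712) and Uty (-0.07 log2, 0.849) were not called, though Kdm5d was with reference centring (-1.56 log2, adjusted p = 0.025) and without ES (-1.20 log2, adjusted p = 0.0314). Lif stood at -0.75 log2 (adjusted p = 0.0247), under the fold minimum.

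The comparison of iPS with ES cells asked how reprogrammed lines differ from an embryo-derived line. In limma's test 0 single genes were called. By list, 16 of 20 primitive endoderm genes were above 0 in iPS minus ES and 38 of 43 fibroblast matrix genes below 0 (camera adjusted p = 3.43e-09 and 5.32e-18; adjusted p = 0.901 for each with an estimated correlation). Gata6, a transcription factor that directs cells to primitive endoderm, was 3.41 log2 above ES in iPS 178B5 and 2.75 log2 above it in iPS 492B4. Lama1, a basement membrane laminin, was 3.40 and 2.76 log2 above ES. Mmp3, a matrix metalloproteinase, stood at -4.58 and -4.50 log2 against ES, and Tnc, tenascin C, at -3.62 and -4.51 log2.

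The smallest adjusted p for a single gene was 0.0529, and 3079 genes had an unadjusted p under 0.05, 592 of them with at least 1 log2. With each array's median set equal 44 genes were called, 15 higher and 29 lower, and with reference centring 166, 54 higher and 112 lower. Without a test, both iPS lines differed from ES by at least 1 log2 in the same direction for 408 genes, 191 higher and 217 lower. The count was 944 without iPS 178B5 (505 and 439) and 548 without iPS 492B4 (285 and 263), which turned the balance. The other leading differences on the higher side were Srgn (4.08 log2, SE 0.16), Nxf7 (3.13 log2, SE 0.14), Cubn (3.12 log2), Tns4 (3.09 log2), Nxf3 (3.07 log2) and Usp26 (2.97 log2). On the lower side they were Mgp (-4.22 log2), Penk (-4.20 log2), Prrx1 (-3.61 log2), Mid1 (-3.61 log2), Prg4 (-3.55 log2) and Cdh11 (-3.54 log2). Among the genes always to be named, Xist stood at -1.46 log2 in iPS minus ES. The Y-linked genes Eif2s3y, Kdm5d and Uty stood at 0.76, 0.59 and 0.33 log2. Of the 7 sex-linked genes measured, 5 were above 0 and 2 below 0 in this difference.

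**Figure D2:**
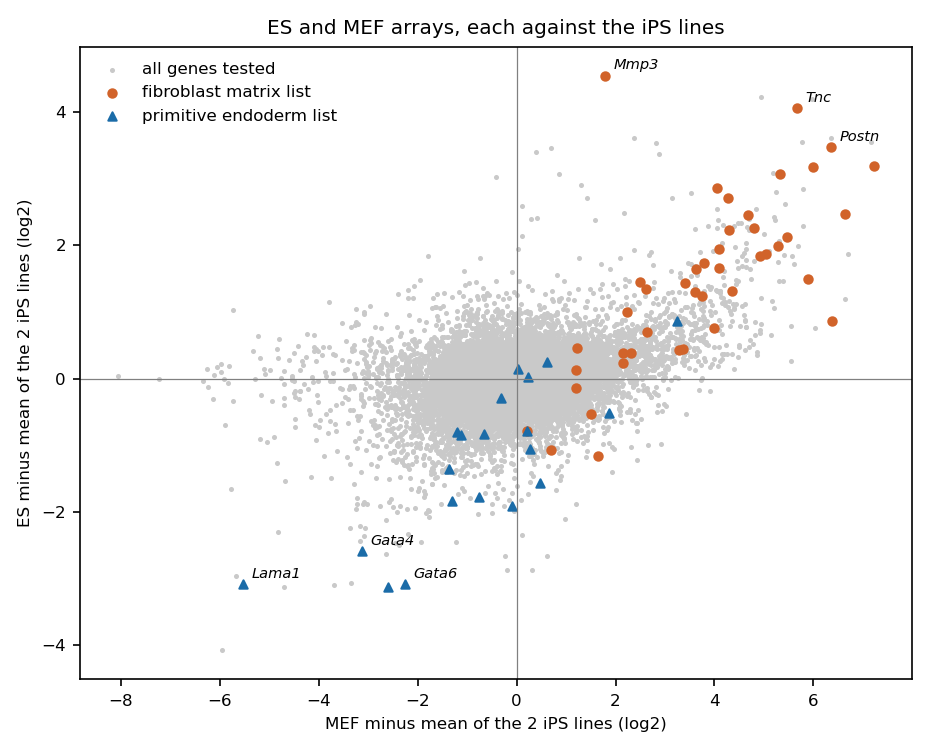
ES minus the mean of the 2 iPS lines (log2, vertical axis) against MEF minus the same mean (log2, horizontal axis), with 1 point per gene, grey for all 19938 genes, circles for the fibroblast matrix list and triangles for the primitive endoderm list. Both axes subtract the same iPS mean. On the vertical axis 38 of 43 fibroblast matrix genes lie above 0, with a median of 1.45 log2, and 16 of 20 primitive endoderm genes lie below 0 on it.

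Fibroblast matrix genes had a median of -1.45 log2 in iPS minus ES and 38 of 43 below 0 (camera adjusted p = 5.32e-18; adjusted p = 0.901 with an estimated correlation). Of these genes 0 were called over all genes, while 27 lower and 2 higher were called adjusted over the list alone. Mesenchymal identity genes had a median of -0.55 log2 and 39 of 44 below 0 (adjusted p = 1.45e-09; adjusted p = 0.901 with an estimated correlation; 13 lower adjusted over the list alone). Hox genes had a median of -0.31 log2 and 33 of 37 below 0 (adjusted p = 1.37e-06; adjusted p = 0.901 with an estimated correlation; 2 lower adjusted over the list alone). Primitive endoderm genes had a median of 0.95 log2 and 16 of 20 above 0, 13 of them by at least 0.5 log2 on both iPS arrays (adjusted p = 3.43e-09; adjusted p = 0.901 with an estimated correlation; 10 higher adjusted over the list alone). Among them Gata4 was 2.59 log2, Col4a1 1.90 log2 and Sox17 1.83 log2 higher, 3 genes chosen after their values were seen.

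Germline genes had a median of 0.38 log2 (adjusted p = 0.000276; adjusted p = 0.901 with an estimated correlation; 3 higher and 1 lower adjusted over the list alone), which was 0.14 log2 without iPS 492B4 and 0.50 log2 without iPS 178B5. Glycolysis genes had a median of 0.23 log2 with 17 of 22 above 0 (adjusted p = 0.000309; adjusted p = 0.901 with an estimated correlation; 2 higher adjusted over the list alone), and the median was 0.13 log2 without iPS 492B4. The p53 and cell cycle inhibitor list had a median of 0.27 log2 (adjusted p = 0.00442; adjusted p = 0.901 with an estimated correlation; 1 higher adjusted over the list alone). Trophoblast genes had a median of -0.45 log2 (adjusted p = 0.00432; adjusted p = 0.901 with an estimated correlation; 0 adjusted over the list alone). Signalling targets had a median of -0.37 log2 (adjusted p = 0.00508; adjusted p = 0.901 with an estimated correlation; 3 lower adjusted over the list alone). Core pluripotency genes had a median of -0.13 log2 with 34 of 46 below 0 (adjusted p = 0.044; adjusted p = 0.901 with an estimated correlation; 0 adjusted over the list alone), and the median was -0.20 log2 without iPS 492B4. Macrophage markers had a median of -0.19 log2 (adjusted p = 0.044; adjusted p = 0.901 with an estimated correlation; 1 higher and 1 lower adjusted over the list alone), and did not pass with reference centring (adjusted p = 0.0714). The other lists did not pass, except that the DNA methylation list was lower over genes with 1 probe set only (adjusted p = 0.0284; adjusted p = 0.926 with an estimated correlation), a choice made after seeing the data. Over all genes its median was -0.23 log2, and -0.10 log2 without iPS 178B5. The cell cycle list (median -0.06 log2) and the primed and early lineage list (median -0.07 log2) had negative medians while camera's direction was up (adjusted p = 0.974 and 0.189), and the medians were -0.01 and -0.03 log2 with equal array medians, -0.12 and -0.13 log2 with reference centring, 0.00 and -0.20 log2 without iPS 178B5, and -0.02 and 0.09 log2 without iPS 492B4.

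Between the 2 iPS lines, with 1 array each, 122 genes stood at least 1 log2 apart, 58 higher and 64 lower on 492B4 (47 and 79 with reference centring), and 4 genes at least 2 log2 apart, without a replicate check. The largest differences with 492B4 higher were Elobl (2.77 log2), Lrrc51 (1.93 log2), Sycp3 (1.73 log2), Stard3nl (1.68 log2), Taf9b (1.62 log2) and Zfand1 (1.54 log2). Those with 492B4 lower were AI506816 (-3.13 log2), Trim12a (-2.49 log2), Alox15 (-2.19 log2), Irgm1 (-1.94 log2), Thbd (-1.87 log2) and Zic2 (-1.84 log2). The meiotic genes Sycp1 and Dazl were 1.27 and 1.15 log2 higher on 492B4, and Lefty1 and Lefty2, inhibitors of Nodal, stood at -1.14 and -1.02 log2. Among other list members, Rab25 (1.24 log2), Pdgfrb (1.24 log2), Aldoc (1.21 log2) and Cubn (1.04 log2) were higher on 492B4, and Zdbf2 (-1.42 log2), Cdh5 (-1.27 log2) and Myc (-1.05 log2) lower.

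By list, 18 of 20 primitive endoderm genes were lower on 492B4 than on 178B5 (median -0.54 log2), as were 28 of 31 primed and early lineage genes (median -0.26 log2). Fibroblast matrix and mesenchymal identity genes had medians of -0.29 and -0.31 log2, and interferon genes -0.19 log2. Each of these 5 medians lay below all 10000 random lists. Those lists matched the size and not the direction of the change against MEF. All 43 fibroblast matrix genes and 43 of 44 mesenchymal identity genes were lower in the lines than on MEF. The random lists also held genes drawn singly, while list members can vary together (estimated correlations 0.602 and 0.510 for these 2 lists against MEF). An extreme percentile is therefore a description and not a test. The p53 and cell cycle inhibitor list had a median of 0.23 log2 with 21 of 25 higher on 492B4, above all random lists. Germline (0.14 log2), epithelial (0.15 log2) and glycolysis (0.16 log2) medians lay at the 99.84, 99.78 and 99.66 percentiles. On the lower side, signalling targets (-0.23 log2, 19 of 27 lower) and endothelial markers (-0.23 log2, 12 of 16 lower) lay at the 0.02 and 0.05 percentiles, and the 2-cell-like (-0.18 log2) and skeletal muscle (-0.14 log2) lists at 0.65 and 1.46.

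**Figure D3:**
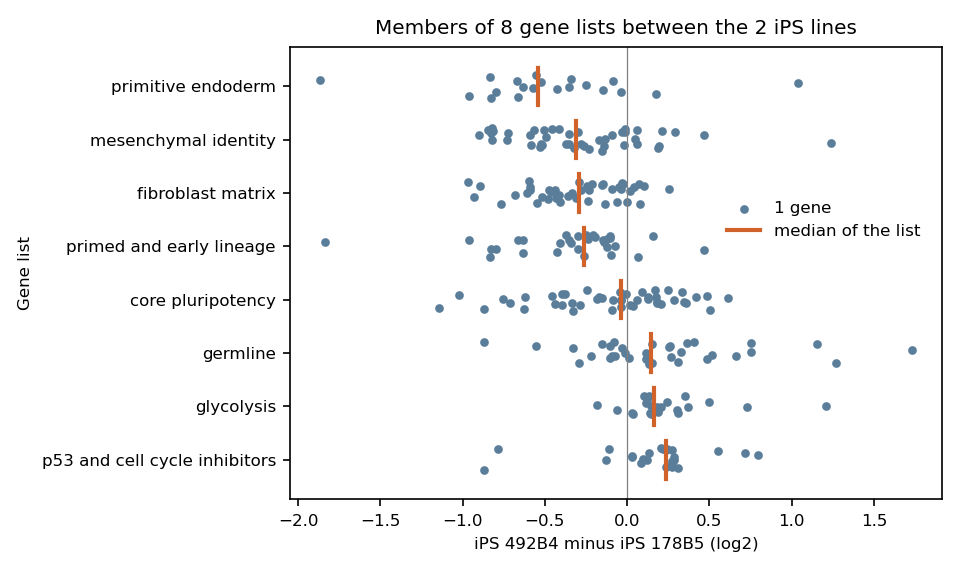
Difference between the 2 iPS arrays (492B4 minus 178B5, log2, horizontal axis) for the measured members of 8 gene lists (vertical axis), with 1 point per gene, scattered vertically within its list for legibility, and a bar at each list's median. The medians run from -0.54 log2 for primitive endoderm genes to 0.23 log2 for the p53 and cell cycle inhibitor list.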

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

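All 8 tests of explanations in this part were chosen after the values they concern had been seen at least in part. For 5 genes both iPS lines stood at least 1 log2 on one side of MEF and ES at least 1 log2 on the other. The iPS minus ES difference was -4.54 log2 for Mmp3, -3.61 log2 for Mid1, -2.90 log2 for Calml4, -2.71 log2 for Mcpt8 and 2.45 log2 for Enpep. None of the 5 passed limma's test of the difference, in which 3079 of all genes had an unadjusted p under 0.05 and 0 were called.

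Of 43 fibroblast matrix genes 38 were higher on the ES array than on the iPS mean, with a median of 1.45 log2 (0 called, camera adjusted p = 0.901 with an estimated correlation). A uniform scaling difference left in the deposited ES values is argued against by the median over all genes, 0.056 log2. The reference genes' median also argues against it, at -0.061 log2 against the iPS arrays. Normalization between arrays brings the all-gene median near 0 in part by design, and a distortion that varies with level was not tested. Cells expressing the primed and early lineage list are argued against by its 29 genes outside the fibroblast lists, unless expression in the iPS cultures masked such cells. Of the 29 genes, 0.0% were at least 0.5 log2 higher on ES than on both iPS arrays. Of all 31, 9 were that much lower on ES, and for these masking is possible. Trophoblast genes went the other way, with 3 of 12 at least 0.5 log2 higher on ES than on both iPS arrays and a median of 0.45 log2, so other lineages are not excluded. Fibroblast RNA in the ES sample, such as from the feeder layer, remains a candidate explanation: of genes at least 4 log2 higher on MEF than on one iPS array, 91.5% in one choice of array and 81.0% in the other were at least 0.5 log2 higher on ES than on the other iPS array. From 1 iPS array to the other, a rise of that size was seen in 20.9% and 0.0% of the same genes. The chosen genes include fibroblast matrix genes in which the pattern was seen, such as Lox and Col12a1, so these shares in part restate it. The share of MEF RNA that would give each gene's value had a median of 6.90% and 6.74% in the 2 choices, with quartiles from 2.77% to 12.4%, and Mmp3 lay above MEF on ES, which MEF RNA alone cannot give. Mesenchymal or trophoblast cells arising in the ES culture, a feeder profile unlike MEF, and strain or line differences were not tested and stay open.

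Of 20 primitive endoderm genes 16 were higher on the iPS mean than on ES and 13 at least 0.5 log2 higher on both iPS arrays (0 called; adjusted p = 3.43e-09; adjusted p = 0.901 with an estimated correlation). Dilution of the ES sample by fibroblast RNA is argued against by the core pluripotency list, whose median difference was -0.127 log2 against 1.20 log2 for the 18 endoderm genes not shared with the fibroblast lists. Endoderm-like cells in the iPS cultures may account for it, as 12 of the 18 genes (66.7%) were at least 0.5 log2 higher on both iPS arrays than on ES. That count rests on the genes in which the pattern was seen, and it does not separate a few differentiated cells from low expression in many cells or from a difference between the lines and strains, which stay open.

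Of 34 germline genes 21 were higher on iPS 492B4 than on iPS 178B5, with a median of 0.14 log2. Scaling of the 2 arrays stays open by the bounds set for its test. The median over all genes was -0.015 log2, opposite in sign to the germline median, which a uniform shift of all genes would not give. The reference genes' median was 0.044 log2 higher on 492B4. The germline median also lay within the root mean square difference between the arrays, 0.276. That bound is a spread of single genes and not of a list's median, so it decides little. Whether the pattern rests on a few members was left undecided, as the 61.8% of members that were higher on 492B4 lay between the bounds set for the test. Sycp3, Sycp1 and Dazl differed by at least 1 log2, which bears on the list's mean (0.21 log2) and not on its median. The median lay at the 99.84 percentile of random lists, but after allowing for the 30 lists looked at the 2-sided share was 0.096, so chance among lists stays open. No biological explanation was tested.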

How the results depend on the processing

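The reference gene centring, the genes with 1 probe set and the count over every probe set were chosen after seeing the data. No gene list that passed and no named gene that was called reversed its direction in the alternatives run. The balance of calls did turn: for iPS against MEF it was 1981 higher and 2235 lower, and 2265 and 2022 with equal array medians. The untested iPS against ES count was 191 higher and 217 lower with both lines, 505 and 439 without iPS 178B5, and 285 and 263 without iPS 492B4. Without 1 line each, the count for pluripotent lines against MEF ran from 1357 (without iPS 178B5) to 4216 (without ES), with 3188 without iPS 492B4 and 1 residual degree of freedom each time, and the untested count for iPS against ES was 944 without iPS 178B5 and 548 without iPS 492B4. For iPS against ES, 0 calls became 44 with array medians set equal, 166 with reference centring, and 408 without a test. For iPS against MEF the count without a fold minimum was 6627 (main 4216), and between the iPS lines the count over every probe set was 199 (main 122), which includes unnamed probe sets. With an estimated correlation 0 of 15 lists against MEF and 0 of 11 lists for iPS against ES passed. That setting rests on 2 and 1 residual degrees of freedom. It has little power, so it cannot tell whether correlated genes account for the lists' results. With the planned variance trend 3563 genes and with the planned probe set rule 3503 genes were called against MEF (main 3512), and 0 for iPS against ES in both. Of 121 genes named or always to be named in the comparison with MEF, 36 lost their call without iPS 178B5, 9 without iPS 492B4, 1 without ES, 3 with reference centring and 2 with equal medians; 3 gained a call without ES and 2 with reference centring. Quantile normalization, a filter at the 75th percentile and raising low values to a bound were planned and not run, because they act on levels and the table held centred differences; no filter is the main setting. No paired analysis was possible because replicate numbers only name the lines. With each array in turn set against the other 3, MEF gave 3512 calls and each of the other arrays 0. When another array stood alone, MEF lay within the group of 3 and widened its spread. That left little room for calls, so the 0 counts do not show that the lines are alike. The 4 splits are also too few for a share under 0.05. Without levels, signal over background could not be judged.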

Other observations

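The hypoxia test in this part was written before its result was seen, for a pattern already seen in the glycolysis list. Values of 5 genes chosen after they were seen, with no list or theme tested, are given here. Fos was 2.21 log2 above MEF on ES and at -0.96 and -0.76 log2 against MEF on iPS 178B5 and iPS 492B4. Fosb was 2.75 log2 above MEF on ES and at -0.82 and -0.59 log2 on the iPS arrays. Egr1 was 0.03 log2 above MEF on ES and at -1.31 and -2.09 log2 on the iPS arrays. None of these 3 was called in limma's test of iPS against ES, with adjusted p of 0.0623, 0.0555 and 0.202. Ccn1 and Ccn2 lay on the other side, 0.53 and 1.08 log2 higher on the iPS mean than on ES, and were not called either.

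Glycolysis genes were higher on iPS 492B4 than on iPS 178B5 (20 of 22) and higher on the iPS mean than on ES (17 of 22, median 0.23 log2 against -0.056 log2 over all genes; adjusted p = 0.901 with an estimated correlation), with a median of 0.13 log2 without 492B4. The hypothesis was a hypoxia response graded over the 3 cultures, tested on 30 hypoxia-responsive genes listed after the pattern was seen. Of them 15 (50.0%) were in the order 492B4 above 178B5 above ES, against 20.1% of all genes. This lay below the 60% set for the hypothesis and above the 30% set against it, so the test decided nothing. Of the 30 genes, 27 were higher on 492B4 than on 178B5, the exceptions being Stc2, Plod2 and Car12 (-0.30, -0.25 and -0.15 log2), and 17 were higher on both iPS arrays than on ES.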
